A study of Mus musculus with 8 samples.

How the data were processed

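Gene expression was measured by RNA sequencing in 8 libraries of c-Kit bead-enriched cells from B16F10 tumours, 4 from scramble and 4 from PERK-deficient tumours. Per the labels, tumours were disaggregated by hand and with liberase and DNase, red cells were lysed, and 100 ng of RNA went into strand-specific libraries read as pairs of 105 bases. Each library came from a tumour of its own; whether each tumour came from a mouse of its own is not stated. The authors' processing notes list bcl2fastq, STAR 2.5.3a, HTSeq 0.6.1 and DESeq2 1.30.1 with the build mm10, without their settings, so the strand setting of the counting and the treatment of overlapping genes are unknown. The deposited raw table holds counts, which are whole numbers per gene and library. The deposited normalized table holds a signal, the counts divided by 1 factor per library, and was used only to check the raw table.

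All 55450 gene identifiers matched GENCODE M21, from which positions were taken. Genes were filtered with filterByExpr by group, which left 16662. Counts were scaled with TMM factors, which ran from 0.863 to 1.03, and tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, ~ group) at a Benjamini-Hochberg adjusted p of 0.05, in R 4.3.3. The biological coefficient of variation was 46.3%. CPM values are TMM-scaled, log2 CPM used a prior count of 2, and ± gives the SD over 4 libraries.

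The 32 gene lists held 705 entries, of which 704 had a symbol in the table. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with adjustment over all lists, and also with an estimated correlation and with fry. Lists added later were adjusted among themselves, not together with these 32. List scores, the mean log2 CPM of tested members, were compared by an exact two-sided permutation test over 70 assignments. Groups of samples were viewed by principal components and Spearman correlations.

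Genes to be named followed a rule: a fixed set; the 10 highest and 10 lowest changes among calls with a mean log2 CPM of at least 1 and no overlap between groups, without predicted genes, pseudogenes and antigen receptor segments; and from each list up to 4 called members with the smallest p, or the 2 most abundant where none was called. From each list but the erythroid and adipocyte ones, the text writes out 1 to 4 of those taken, chosen after their values were seen. Preference went to calls that did not change with the settings.

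Alternatives were DESeq2 1.42.0, voom with quality weights, RLE, upper-quartile and total-count scaling, no and stricter filters, a fit that is not robust, at least 2-fold changes, a melanocyte covariate, a replicate block, and leaving out each library. Settings added later left out PERK_KO libraries 2 and 3, PERK_KO library 4 with scramble library 4, or mitochondrial genes, or used a pan-leukocyte covariate. On simulated data with 200 changed genes among 16662, the test recovered 32, 66, 74 and 76% of genes changed 1.5-, 2-, 4- and 8-fold, and called 9 of 16462 unchanged genes. The changed genes were drawn above a minimum mean CPM, and genes were simulated independently of each other. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 matplotlib 3.10.9 and, in R, the package data.table (version 1.17.8).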

Results

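RNA was sequenced from c-Kit-enriched cells of B16F10 melanomas grown in wild-type C57BL/6 mice. B16F10 is a pigmented mouse melanoma line, and c-Kit is a growth factor receptor carried by blood cell precursors, mast cells and cells of the melanocyte lineage. Mice aged 6 weeks received 150000 tumour cells under the skin, and tumours were removed on day 17. The injected cells were either a scramble control line or a line lacking PERK, a kinase of the endoplasmic reticulum that slows translation under protein-folding stress. After digestion of each tumour, c-Kit-positive cells were enriched on magnetic beads and not by flow sorting. There were 4 libraries from scramble tumours, numbered 2 to 5, and 4 from PERK-deficient tumours, numbered 1 to 4, each from a tumour of its own. Library totals ran from 44950033 to 56697163 counts in scramble tumours and from 29006949 to 47530393 counts in PERK-deficient tumours. A floor of 3 counts corresponded to 0.103 CPM (counts scaled to a common library total, the unit used throughout) in the shallowest library and 0.0529 CPM in the deepest. Floors and intervals of this kind cover counting error only.

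The comparison asked which transcripts of the c-Kit-enriched fraction differ when the tumour cells lack PERK. Eif2ak3, which encodes PERK (ENSMUSG00000031668.14, mm10 chromosome 6, 70844515 to 70905245), fell by 1.97 on the log2 scale (SE 0.31, n = 4 and 4, edgeR adjusted p = 0.00371). Its level was 53.4, 56.4, 59.2 and 48.3 CPM in the scramble libraries 2 to 5 and 8.61, 7.73, 22.7 and 16.3 CPM in the PERK-deficient libraries 1 to 4. All 8 libraries therefore matched their labels. Kit, the receptor used for enrichment (ENSMUSG00000005672.12, chromosome 5, 75574916 to 75656722), had 196 ± 23.7 CPM (SD, n = 4) in scramble and 175 ± 37.8 CPM (n = 4) in PERK-deficient tumours. The Kit difference did not pass the test (edgeR adjusted p = 0.559). Transcripts of the melanocyte lineage were abundant in both groups. The 23 tested melanocyte lineage markers together took 27250 ± 318 CPM (n = 4) in scramble and 20414 ± 1742 CPM (n = 4) in PERK-deficient tumours.

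At a preset correlation, lists of leukocyte, antigen presentation and interferon-stimulated genes were higher and the melanocyte lineage list was lower in PERK-deficient tumours. None of these lists passed with an estimated correlation. Of 16662 genes tested, 1277 were higher and 1022 lower in PERK-deficient tumours at an edgeR adjusted p under 0.05. At a change of at least 2-fold, 919 were higher and 130 lower. The libraries of the groups did not overlap at 3550 genes, 21.3% of those tested, against 2.86% by chance. The count of calls was 1078 without scramble replicate 3, 1283 without scramble replicate 2, 1361 without scramble replicate 5 and 1428 without scramble replicate 4. Upper-quartile factors in place of TMM gave 1430 higher and 653 lower genes, so that 68.7% of calls were higher against 55.5% with TMM. Library totals alone gave 1065 higher and 1169 lower genes, 47.7% higher, so which direction held more calls depended on the scaling.

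**Figure D1:**
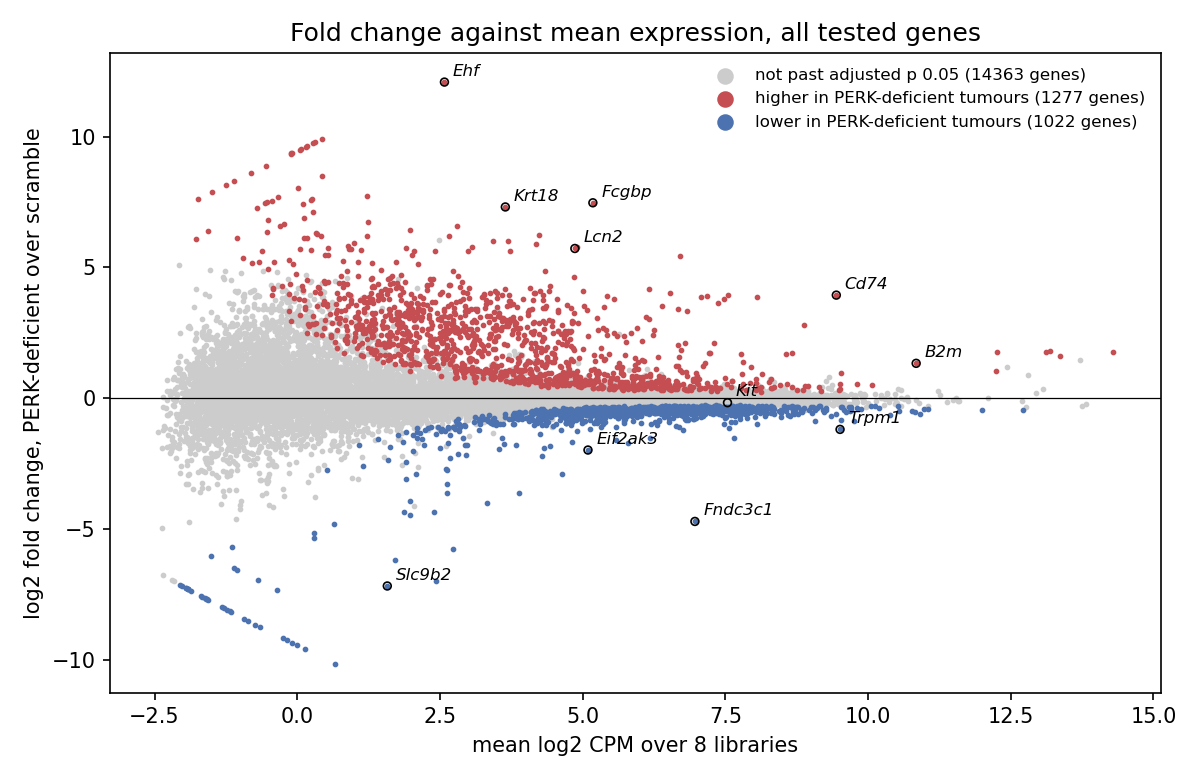
Log2 fold change of PERK-deficient over scramble tumours (y axis) against mean log2 CPM over the 8 libraries (x axis) for the 16662 tested genes, with each call coloured by direction. The 919 higher calls of at least 2-fold outnumber the 130 lower ones; points on the straight diagonals are genes without a count in a whole group, whose fitted size depends on the prior count.

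Among the 10 highest calls under the fixed rule, Ehf, an epithelial transcription factor, had no count in the scramble libraries and 11.9 ± 6.83 CPM (n = 4) in PERK-deficient tumours, at least 838-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.000134). Krt7 and Krt18, keratins of simple epithelium, rose by 7.74 and 7.31 on the log2 scale (SE 1.07 and 0.87, edgeR adjusted p = 0.00153 and 0.00194). Cldn3 and Cldn4, tight junction proteins, rose by 6.20 and 6.44, and the mucin Muc4 rose by 6.74. Csn3, the milk protein kappa-casein, went from 0.479 to 37.2 CPM and Wfdc18 from 0.140 to 13.8 CPM. Fcgbp, which encodes a mucin-like protein, rose by 7.47 and Mpzl2, a junctional adhesion protein, by 6.20. Muc4 and Krt7 had 9 and 4 counts over the scramble group, so the sizes of their folds are loosely set. The Muc4 counts lay in scramble library 3, and those of Krt7 in scramble library 2, without which that group has none. Other folds also moved by more than 1.5 times with 1 library. The log2 change became 8.04 for Krt18 without scramble replicate 3, 7.06 for Cldn4 and 7.73 for Mpzl2 without scramble replicate 2, and 7.89 for Wfdc18 and 9.18 for Cldn3 without scramble replicate 5. Without PERK_KO replicate 4 it was 5.80 for Cldn4 and 5.41 for Mpzl2.

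By the rule that chose them, the 10 lowest calls were lower in every PERK-deficient library than in any scramble library. Fndc3c1 (X chromosome, 106420041 to 106485401) fell by 4.70 on the log2 scale (SE 0.23, edgeR adjusted p = 5.31e-06), from 241 ± 17.0 to 9.34 ± 3.38 CPM (SD, n = 4 and 4). Slc9b2, a sodium/hydrogen exchanger, fell from 5.81 to 0.0348 CPM and Fstl4 from 10.6 to 0.0755 CPM, and without PERK-deficient library 3 that group has no count of either gene. Without PERK_KO replicate 1 the log2 change was -6.55 for Mmp16 and -4.59 for Pou3f2, without PERK_KO replicate 3 it was -6.06 for Naalad2 and -6.22 for Tph2, and without PERK_KO replicate 4 it was -8.30 for Armh4. Mmp16, a membrane-bound matrix metalloproteinase, fell by 5.73 and Armh4 by 6.18 on the log2 scale. The transcription factors Hoxd13 and Pou3f2 fell by 4.46 and 3.90. Naalad2 fell by 4.35, Tph2, a serotonin synthesis enzyme of neurons, by 4.32, and Raet1e, a ligand of the receptor NKG2D, by 4.00. Raet1e has near-identical neighbours and its count is uncertain. Its call ended without scramble replicate 3 (edgeR adjusted p = 0.0527), as did that of Naalad2 without scramble replicates 2 or 3 (adjusted p = 0.0524 and 0.0575). The Tph2 call ended in 5 of the 8 sets that leave out a library, with adjusted p = 0.0612, 0.0724, 0.0524 and 0.0636 without scramble replicates 2, 3, 4 and 5 and 0.0509 without PERK_KO replicate 4.

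**Figure D2:**
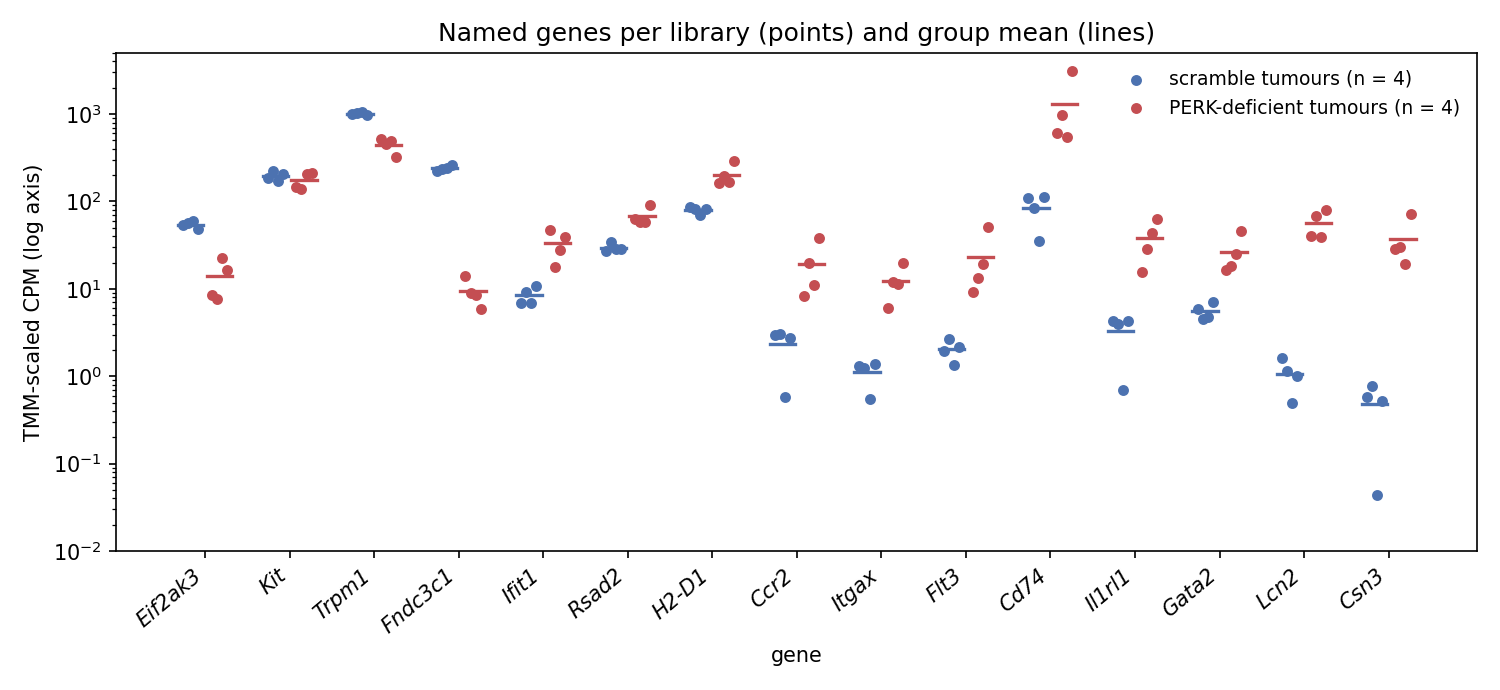
TMM-scaled CPM (log axis) of 15 named genes, with a point per library and a line at each group mean (n = 4 per group). Eif2ak3, Trpm1 and Fndc3c1 lie lower in every PERK-deficient library, Kit overlaps between the groups, and the remaining 11 genes lie higher in every PERK-deficient library.

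Gene lists were fixed before the data were examined. Member counts below are of genes that passed the filter. These were 9 of 20 listed for cytotoxic and NK cells, 13 of 23 for T cells and 14 of 20 for B cells. They were 5 of 15 for basophils and eosinophils, 7 of 15 for platelets and 6 of 16 for keratinocytes. Skeletal muscle, erythroid, adipocyte and neutrophil lists kept 9 of 15, 7 of 18, 5 of 15 and 12 of 23. Of 32 lists, camera at its preset correlation placed 22 higher and 3 lower in PERK-deficient tumours, and none passed with a correlation estimated per list. The mean log2 CPM of 20 lists separated the groups at p = 0.0286 (adjusted p = 0.0457), the smallest that the exact two-sided permutation test over 70 assignments can give. With the melanocyte score as a covariate 9 lists passed camera and 15 turned direction, and with the mean of 19 tested pan-leukocyte genes, chosen after the data were seen, 8 passed and 8 turned. Between the groups lay 95.7% of the variance of the melanocyte score and 74.6% of that of the pan-leukocyte score, so these covariates take up much of the group difference.

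**Figure D3:**
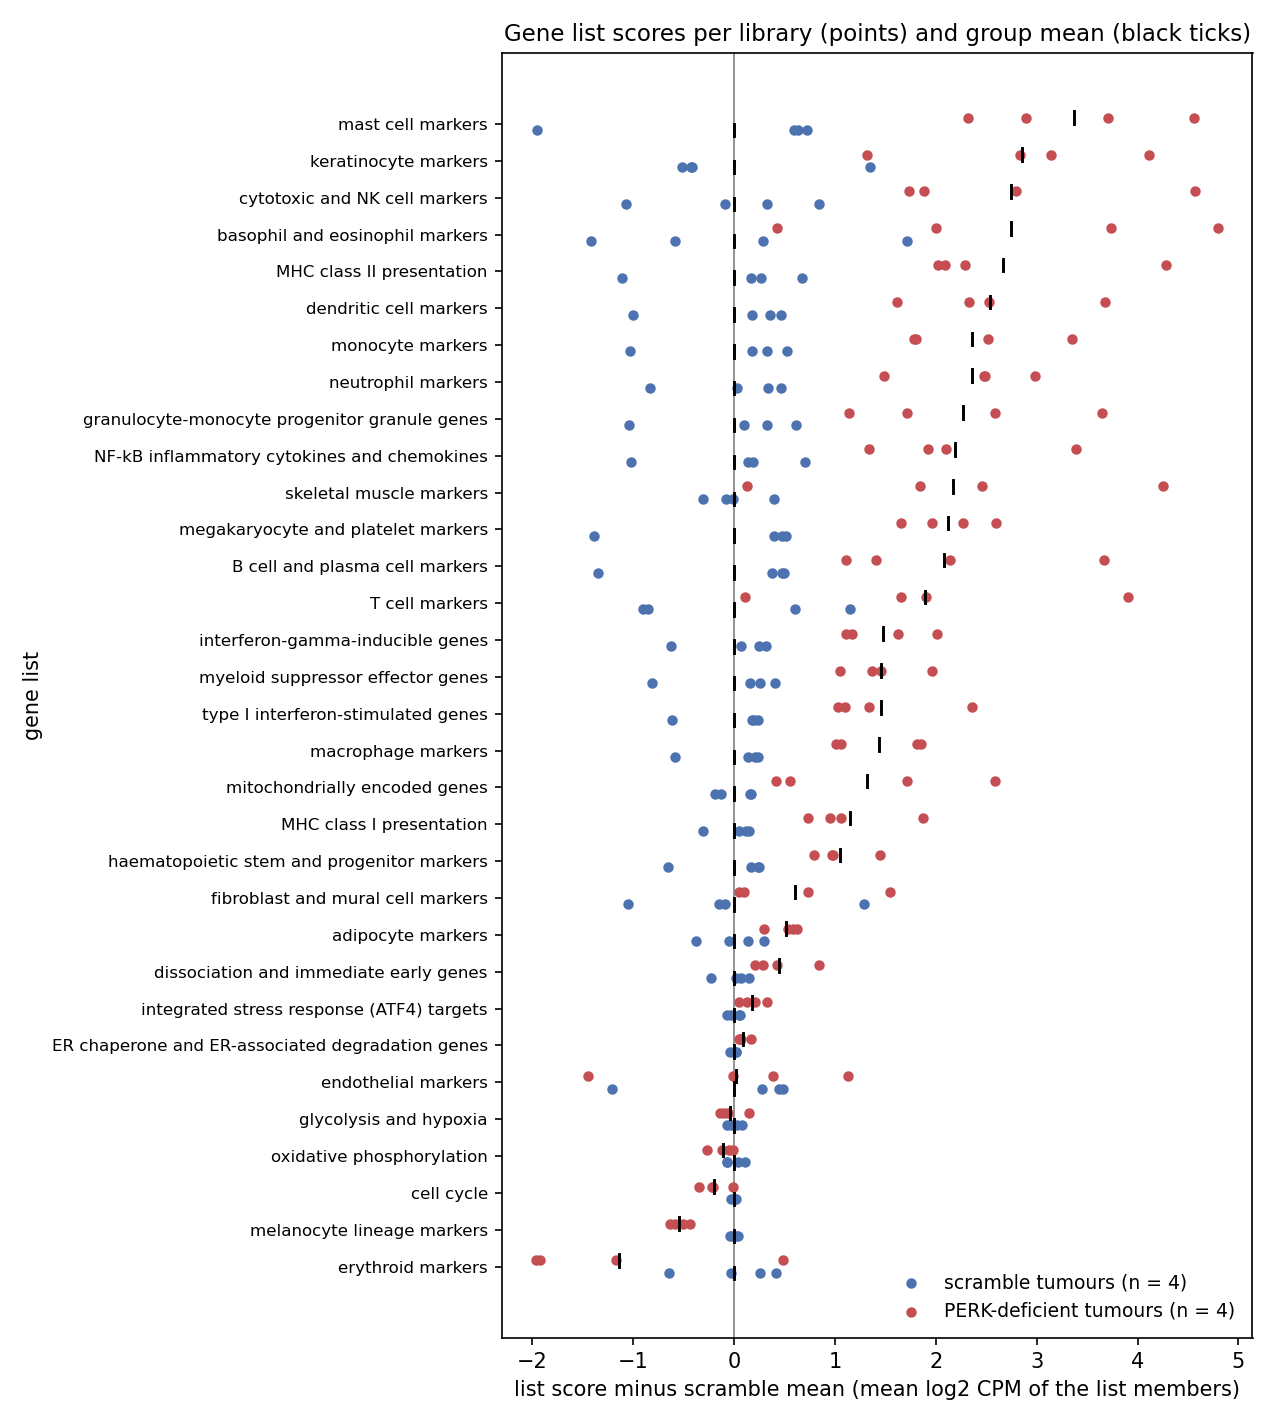
Mean log2 CPM of each of the 32 gene lists minus its scramble mean (x axis), with a point per library (n = 4 per group) and a black tick at each group mean. Mast cell markers lie 3.37 higher and melanocyte lineage markers 0.54 lower in PERK-deficient tumours, and the endothelial scores of the groups overlap.

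Of 41 type I interferon-stimulated genes, 23 rose and none fell, and 32 rose when adjusted over the list alone. Their median log2 change was 1.19 (camera adjusted p = 8.04e-16, and adjusted p = 0.189 with an estimated correlation). Rsad2, which encodes the antiviral protein viperin, rose by 1.19 (SE 0.15), Ifit1, which binds foreign RNA, by 1.97 (SE 0.28), and Isg15, a ubiquitin-like protein, by 1.54 (SE 0.30), with edgeR adjusted p = 0.000917, 0.00161 and 0.00828. Trim30a rose by 2.15. Irf7, the transcription factor that amplifies interferon production, had 6.75 ± 2.12 CPM (n = 4) in scramble and 32.9 ± 32.1 CPM (n = 4) in PERK-deficient tumours (edgeR adjusted p = 0.0594). Irf7 passed without PERK_KO replicate 1, 3 or 4 (adjusted p = 0.0242, 0.0263 and 0.033), but its log2 difference of 2.28 became 1.36 without PERK_KO replicate 4. With all 8 libraries it passed with DESeq2 (adjusted p = 0.00711), with limma-voom (0.0234) and in the edgeR fit that is not robust (0.0243). Ifnar1, a subunit of the type I interferon receptor, fell by 0.49 (SE 0.10, adjusted p = 0.00811). The list's call ended, with its direction turned, when the pan-leukocyte mean was in the model (camera adjusted p = 0.786), and it turned lower with the melanocyte score (camera adjusted p = 0.0243). In the same libraries the pan-leukocyte score was 2.40 higher on the log2 scale in PERK-deficient tumours (exact permutation p = 0.0286).

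Of 22 tested interferon-gamma-inducible genes, 12 rose over all genes and 15 when adjusted over the list alone (camera adjusted p = 6.33e-09, and adjusted p = 0.166 with an estimated correlation). Ido1, which degrades tryptophan, had no count in scramble and 2.65 ± 1.6 CPM in PERK-deficient tumours, at least 187-fold higher against the floor (edgeR adjusted p = 0.0022). Nlrc5, the transactivator of MHC class I genes, rose by 1.38 (SE 0.27) and Iigp1, an immunity-related GTPase, by 2.11 (SE 0.42). Of 20 MHC class I presentation genes, 11 rose, also 11 when adjusted over the list alone (camera adjusted p = 1.74e-10, and adjusted p = 0.179 with an estimated correlation). B2m went from 1039.6 ± 152 to 2634 ± 734 CPM and H2-D1 from 80.2 ± 7.16 to 203 ± 58.1 CPM (SD, n = 4 and 4), and the peptide transporter Tap1 rose by 1.81. Reads of H2 genes may be split between near-identical copies by the authors' counting. Of 15 MHC class II presentation genes, 11 rose and 13 when adjusted over the list alone, with a median of 3.19 (camera adjusted p = 1.74e-10, and adjusted p = 0.189 with an estimated correlation). Among them H2-Ab1 rose by 3.92 (SE 0.71), from 18.03 ± 6.48 to 273 ± 267 CPM (SD, n = 4 and 4). Its level was 109, 189, 124 and 671 CPM in the PERK-deficient libraries 1 to 4, and its log2 change was 2.96 without PERK_KO replicate 4.

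Of 21 monocyte markers, 16 rose, also 16 when adjusted over the list alone, with a median of 2.64 (camera adjusted p = 2.22e-14, and adjusted p = 0.166 with an estimated correlation). Ccr2, the receptor that draws monocytes from blood, went from 2.33 ± 1.17 to 19.3 ± 13.3 CPM (edgeR adjusted p = 0.011), and Cd14 and F13a1 rose by 2.41 each. Of 22 dendritic cell markers, 15 rose and 18 when adjusted over the list alone, with a median of 3.19 (camera adjusted p = 5.24e-16, and adjusted p = 0.166 with an estimated correlation). Itgax, which encodes CD11c, rose by 3.44 (SE 0.42) and Flt3, the receptor for a dendritic cell growth factor, by 3.52 (SE 0.53). Of 24 macrophage markers, 17 rose and 18 when adjusted over the list alone (camera adjusted p = 2.08e-13, and adjusted p = 0.166 with an estimated correlation), among them Folr2 by 2.94 and Pf4 by 2.58. Of the fixed single genes, Csf1r rose by 2.32, Ly6c2 by 3.67, Irf8 by 3.54 and Itgam by 1.83. Without PERK_KO replicate 4 the change of Ly6c2 was 2.61, that of Irf8 2.74 and that of Flt3 2.78. Without scramble replicate 3 the calls of these 4 fixed genes ended (edgeR adjusted p = 0.0667, 0.0653, 0.0501 and 0.0662). Without scramble replicate 5 those of Irf8 and Itgam ended (adjusted p = 0.0511 and 0.0796), and without PERK_KO replicate 4 that of Itgam (0.0772).

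Of 12 tested neutrophil markers, 5 rose and 6 when adjusted over the list alone (camera adjusted p = 1.68e-08, and adjusted p = 0.129 with an estimated correlation). Among them were Lcn2 (5.73, SE 0.38) and Ltf (4.34, SE 0.51), secreted iron-binding proteins that glandular epithelium also makes. Of 21 myeloid suppressor effector genes, 12 rose and 1 fell, and 13 rose and 1 fell when adjusted over the list alone (camera adjusted p = 3.05e-08, and adjusted p = 0.166 with an estimated correlation). Ncf1, a subunit of the phagocyte oxidase, rose by 2.503, Lgals9 by 0.68, and Hif1a, the oxygen-regulated transcription factor, fell by 0.45. Of 23 NF-kB inflammatory cytokines and chemokines, 15 rose and 17 when adjusted over the list alone (camera adjusted p = 7.15e-13, and adjusted p = 0.179 with an estimated correlation). Cxcl16 rose by 2.79, Ccl8 by 3.61, and the feedback inhibitors Tnfaip3 and Nfkbia by 2.06 and 1.61.

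Camera at the preset correlation also placed lists of mast cells, blood progenitors and some other blood lineages higher. Of 17 mast cell markers, 14 rose and 16 when adjusted over the list alone, with a median of 3.51 (camera adjusted p = 7.27e-14, and adjusted p = 0.179 with an estimated correlation). Il1rl1, the receptor for interleukin 33, went from 3.30 ± 1.75 to 37.9 ± 20.7 CPM, and Ms4a2, a chain of the IgE receptor, rose by 3.44 (SE 0.65). Of 24 haematopoietic stem and progenitor markers, 8 rose and 9 when adjusted over the list alone (camera adjusted p = 4.70e-05, and adjusted p = 0.179 with an estimated correlation). Gata2, a transcription factor of blood progenitors and mast cells, rose by 2.24 (SE 0.32), Lmo2 by 2.32 and Runx1 by 0.90. Of the 16 members of the granulocyte-monocyte progenitor granule list 9 were tested, and 4 rose, also 4 when adjusted over the list alone (camera adjusted p = 1.16e-05, and adjusted p = 0.179 with an estimated correlation). Among the 4 were Serpinb1a (3.75) and Clec12a (3.97, and 3.23 without PERK_KO replicate 4). The called members also included receptor chains, so the calls do not show a rise of granule genes as such. Of 7 megakaryocyte and platelet markers, 3 rose and 4 when adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.166 with an estimated correlation). One of these was Rab27b (3.64, SE 0.75), a granule transport protein that mast cells also use. Of 5 basophil and eosinophil markers, 1 rose, also 1 when adjusted over the list alone: Cd200r3, by 3.63 (list camera adjusted p = 0.0137, and adjusted p = 0.315 with an estimated correlation). This list's call ended without PERK_KO replicate 4 (camera adjusted p = 0.0615). Its tested members together took 1.09 CPM in scramble tumours, so they had little room to fall.

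Among lymphocyte lists, none of 13 T cell markers passed, also none when adjusted over the list alone, while camera placed the list higher (adjusted p = 0.00502, and adjusted p = 0.388 with an estimated correlation). Cd3e had 0.527 ± 0.355 CPM (n = 4) in scramble and 2.29 ± 3.06 CPM (n = 4) in PERK-deficient tumours (edgeR adjusted p = 0.212), and its log2 difference of 2.11 became 0.57 without PERK_KO replicate 4. Tcf7, which encodes TCF1, had 26.8 ± 2.13 and 35.2 ± 7.79 CPM (adjusted p = 0.131), and passed without PERK_KO replicate 3 (adjusted p = 0.0171). The T cell list's call ended without PERK_KO replicate 4 (camera adjusted p = 0.0857). Of 9 tested cytotoxic and NK cell markers, 5 rose and 7 when adjusted over the list alone (camera adjusted p = 7.19e-06, and adjusted p = 0.193 with an estimated correlation). Among them the chemokine Ccl5 rose by 2.88 (SE 0.37) and Klrk1, the receptor NKG2D, by 4.34 (SE 0.80). The 9 tested markers together took 6.73 CPM in scramble tumours, so they had little room to fall. The Klrk1 change was 3.17 without PERK_KO replicate 4. Of 14 B cell and plasma cell markers, 3 rose, also 3 when adjusted over the list alone (camera adjusted p = 0.000196, and adjusted p = 0.277 with an estimated correlation). Igkc, the kappa light chain constant region, went from 2.09 ± 1.22 to 28.9 ± 19.4 CPM.

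Lists of stromal and other tissue cells did not all move one way. None of 20 endothelial markers passed, also none when adjusted over the list alone, and the list score differed by 0.02 (exact permutation p = 1; camera adjusted p = 0.435). The direction of the list turned without scramble replicate 4 (camera adjusted p = 0.542) and PERK_KO replicate 3 (0.793), and its score difference became -0.38, -0.11 and -0.35 without scramble replicate 4, PERK_KO replicate 2 and PERK_KO replicate 3. Cdh5, the cadherin of vascular endothelium, had 71.1 ± 37.1 and 86.0 ± 37.5 CPM, and its log2 difference of 0.28 became -0.0606 without scramble replicate 4. Of 20 fibroblast and mural cell markers, 1 rose (Lum, by 1.73) and none when adjusted over the list alone (camera adjusted p = 0.0766). The Lum call ended without scramble replicates 2, 3, 4 or 5 (edgeR adjusted p = 0.0901, 0.103, 0.087 and 0.0963) and without PERK_KO replicate 3 (0.0536). The list passed without scramble replicate 2 (8.92e-05) and without PERK_KO replicate 1 (0.0463). None of 7 erythroid markers passed, also none when adjusted over the list alone (camera adjusted p = 0.396), and none of 5 adipocyte markers in either way (camera adjusted p = 0.293). Of 6 tested keratinocyte markers, 3 rose, also 3 when adjusted over the list alone (camera adjusted p = 3.44e-05, and adjusted p = 0.166 with an estimated correlation). One of these was Epcam (5.77, SE 0.49), an adhesion molecule of simple epithelium. The 6 tested markers together took 4.30 CPM in scramble tumours, so they had little room to fall. None of 9 skeletal muscle markers rose over all genes, and 5 did when adjusted over the list alone (camera adjusted p = 0.0156, and adjusted p = 0.315 with an estimated correlation). Myh4, the fast muscle myosin, had 0.167 ± 0.254 CPM in scramble and 10.9 ± 13.3 CPM in PERK-deficient tumours (edgeR adjusted p = 0.0738), with 30.2 CPM in PERK_KO library 3. Its log2 difference of 6.07 became 7.92 without scramble replicate 4 and 4.75 without PERK_KO replicate 3. It passed with DESeq2 (adjusted p = 0.0206), in the edgeR fit that is not robust (0.029), and without scramble replicate 4 (0.0495) or PERK_KO replicate 2 (0.0167). The muscle list's call ended without PERK_KO replicate 3 (camera adjusted p = 0.0837). Its tested members together took 5.86 CPM in scramble tumours, so they had little room to fall.

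Of 23 tested melanocyte lineage markers, 14 fell and 18 when adjusted over the list alone, with a median of -0.48 (camera adjusted p = 3.60e-13, and adjusted p = 0.129 with an estimated correlation). Trpm1, an ion channel of melanocytes, fell from 1012 ± 33.4 to 446 ± 86.2 CPM. Oca2, a melanosome transporter, fell by 1.57 (SE 0.16) and Mc1r, the melanocortin receptor, by 0.79 (SE 0.09). Trpm1 and Oca2 lie on chromosome 7, whose expressed genes were lower in PERK-deficient tumours with a median of -0.36. The melanocyte markers on other chromosomes had a median of -0.43. Of 32 cell cycle genes, 4 fell, also 4 when adjusted over the list alone (camera adjusted p = 0.000849, and adjusted p = 0.388 with an estimated correlation), among them the mitotic kinase Plk1 (-0.54, SE 0.08). Without PERK_KO replicates 2 and 3 together, a set chosen after the data were seen, this list's call ended (camera adjusted p = 0.0985). Of 32 oxidative phosphorylation genes, 5 fell and 6 when adjusted over the list alone (camera adjusted p = 0.0352, and adjusted p = 0.546 with an estimated correlation), among them Ndufs1 by 0.40. That list's call ended with upper-quartile factors (0.0739) or RLE factors (0.0774), and without scramble replicate 4 (0.053), scramble replicate 5 (0.147) or PERK_KO replicate 3 (0.29). Of 22 glycolysis and hypoxia genes, 1 rose and 5 fell, also 1 and 5 when adjusted over the list alone (camera adjusted p = 0.293). The glycolytic enzymes Ldha, Gpi1 and Eno1 fell by 0.48, 0.60 and 0.40, and Egln3, a hypoxia-induced hydroxylase, rose by 1.29. This list passed without PERK_KO replicate 2 (camera adjusted p = 0.018).

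Neither of the lists tied to PERK signalling and protein folding passed camera, which tests for a shared direction. The mixed test of fry, which takes changes in either direction, passed both. Its adjusted p was 3.78e-08 for the integrated stress response list and 7.42e-05 for the ER list. Most other lists passed the mixed test too. Of 30 integrated stress response genes driven by ATF4, 3 rose and 2 fell, also 3 and 2 when adjusted over the list alone (camera adjusted p = 0.225), although the list passed without PERK_KO replicate 3 (0.0374). Stc2, a secreted glycoprotein, rose by 3.90 (SE 0.38) and the transcription factor Atf3 by 1.18 (SE 0.18), while Vldlr fell by 1.51 (SE 0.23). Of 26 ER chaperone and ER-associated degradation genes, 2 rose and 4 fell over all genes, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.213). The mean log2 CPM of this list was 7.24 in scramble and 7.33 in PERK-deficient tumours, higher in all 4 (exact permutation p = 0.0286, adjusted p = 0.0457). Without scramble replicate 2, 3, 4 or 5 that exact permutation p was 0.0571 each time. Creld2, an ER stress-induced chaperone, rose by 0.45 (SE 0.09). Of 22 dissociation and immediate early genes, 9 rose and 1 fell, and 9 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00423, and adjusted p = 0.388 with an estimated correlation). Egr1 and Zfp36, both induced within minutes of stress, rose by 1.71 (SE 0.31) and 1.72 (SE 0.32).

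Of 12 mitochondrially encoded genes, 8 rose and 9 when adjusted over the list alone (camera adjusted p = 8.94e-06, and adjusted p = 0.315 with an estimated correlation). All genes with names starting with mt-, not only those of the list, held 4.13, 3.71, 4.50 and 4.30% of counts in the scramble libraries. In the PERK-deficient libraries 1 to 4 they held 5.22, 19.2, 13.9 and 6.89%. mt-Nd2, a subunit of complex I, went from 4033 ± 577 to 13674 ± 9197 CPM (edgeR adjusted p = 0.0372). Its call ended without scramble replicates 2, 3, 4 or 5 (adjusted p = 0.102, 0.115, 0.052 and 0.0832) and without PERK_KO replicate 3 (0.057). Without PERK-deficient libraries 2 and 3, which held the highest shares, 1306 genes were higher and 1307 lower, and 23 of the 32 lists passed camera. The type I interferon list then had a median of 1.47 and the mast cell list one of 3.73.

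The first principal component held 39.3% of the variance of log2 CPM and separated the groups. It ran from -99.9 to -56.2 in scramble libraries and from 28.6 to 129 in PERK-deficient libraries, with scramble library 4 and PERK-deficient library 4 at its ends. The Spearman correlation across genes was 0.980 to 0.987 between scramble libraries, 0.957 to 0.969 between PERK-deficient libraries and 0.907 to 0.964 between groups. The PERK-deficient libraries therefore differed more among themselves than the scramble libraries did. Without PERK-deficient library 4 and scramble library 4, left out together after the data were seen, 779 genes were higher and 500 lower.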

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

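All tests on explanations of the leukocyte pattern, those on skin keratinocytes, dilution and copy number, and the lists of pan-leukocyte and simple epithelial genes were chosen after the data were seen; the tests on gland epithelium, on GC content and length, and on other splits of the libraries were set before their results.

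Of 340 groups of 4 libraries tested, 38 held a library whose gap to its nearest neighbour over the group's range exceeded Dixon's 95% critical value, where chance gives about 17. Scramble library 4 stood below its group 13 times. Its values in CPM were Ccr2 0.585, Itgax 0.542, Trim30a 4.07, Il1rl1 0.693, Cdh5 15.9 and Ccl8 0.650. Its list scores in log2 CPM were type I interferon-stimulated genes 1.98, macrophage 3.65, haematopoietic stem and progenitor 2.48, mast cell -0.77, B cell and plasma cell -2.85, endothelial 1.34, and megakaryocyte and platelet -1.98. PERK_KO library 4 stood above its group 10 times, with Ehf at 22.1, Armh4 0.286, H2-T23 28.6, H2-Ob 16.8, Cd74 3095, H2-Ab1 671, Serpinb1a 59.6, Clec12a 12.2 and Klrk1 24.4 CPM, and an MHC class II score of 5.98. These genes and lists are expressed together, so the values within a library are not independent of each other.

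In scramble library 2, Krt7 (0.0724 CPM), Jchain (0.163 CPM) and the keratinocyte score (-0.33) were above and the cell cycle score (6.94) below the others. Scramble library 3 was above at Muc4 (0.155 CPM). Scramble library 5 was above at Cldn3 (0.619), Ltf (1.06) and Csf2ra (29.5) and below at Lum (0.677) and Phgdh (52.3 CPM). PERK_KO library 3 was above at Slc9b2 (0.139), Fstl4 (0.302), Oca2 (33.2) and Ttn (37.7 CPM), and PERK_KO library 2 at Fscn1 (409 CPM). Krt7, Jchain and Muc4 had no count in the other scramble libraries, and Slc9b2 and Fstl4 had none in the other PERK-deficient libraries.

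Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many called genes: 2299 against at most 0 in any other split (at most 1623 at an unadjusted p under 0.05, against 4448). The real split is 2.86% of the splits, the smallest share that 35 splits can give, and every other split mixed libraries of both groups. Chance is therefore less likely for the count of genes, but the splits cannot exclude it. For the count of gene lists, 5 of the 35 splits gave as many as the real 25, and the highest other split gave 27, so chance stays open there.

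Leukocyte lists were higher in PERK-deficient tumours, with 16 of 19 tested pan-leukocyte genes called higher. Their camera adjusted p with an estimated correlation was 0.062, adjusted over the lists added later only. A lower share of tumour RNA would raise endothelial genes alike, but the pan-leukocyte minus endothelial score was 2.38 higher (exact permutation p = 0.0286). Leukocyte genes thus rose more than endothelial genes, although the score was only 0.0261 in PERK_KO library 3. The test was chosen after both scores had been seen, and the endothelial score had no steady direction across settings. It therefore cannot decide on a lower share of tumour RNA. The high mitochondrial share of PERK_KO libraries 2 and 3 is argued against by the 16 genes still called higher without them, with a median of 3.24 against 2.88. Whether a larger leukocyte share accounts for the whole change in interferon-stimulated genes cannot be told apart from regulation within cells, because the pan-leukocyte score lies 74.6% between the groups; with it in the model the list's camera adjusted p was 0.786, against 1.28e-19 to 0.786 over the settings run. Loss of PERK in the tumour cells, the difference the design names, may underlie the leukocyte change and stays open with differences of tumour size or of the lines, which were not measured here.

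Several epithelial genes were higher in PERK-deficient tumours. RNA of gland epithelium would raise other simple epithelial genes too. Of 15 tested, among 20 listed, 8 were higher (13 when adjusted over the list alone, median 2.99). Their camera adjusted p with an estimated correlation was 0.0243, adjusted over the lists added later only. The share of 8 higher genes reaches the 0.5 set for the test over the tested genes and misses it over the listed genes. That last count was chosen after the values were seen, so the source stays open. Only 4 of the 15, none of them in another list, reached 1 CPM in scramble libraries, and the others had little room to fall: of the 4, Muc1 passed and Cgn, Tjp3 and Spint1 did not (edgeR adjusted p = 0.213, 0.732 and 0.125). The skin keratins Krt5, Krt14, Krt1 and Krt10 together gained 2.17 CPM, 2.88% of the 75.3 CPM gained by Krt7, Krt8, Krt18 and Krt19. Skin keratins thus gained far less than these simple keratins. Krt7 and Krt18 had already stood among the 10 highest calls, so the share cannot decide on skin keratinocytes as a source. Krt5 and Krt14 went from 9 to 192 and from 12 to 143 counts, Krt10 from 8 to 0, and Krt1 had 0 counts. Of the keratinocyte list, 3 of 6 tested genes were higher, Epcam of simple epithelium among them (camera adjusted p = 3.44e-05, and adjusted p = 0.166 with an estimated correlation). Gland tissue taken with the tumour, which the c-Kit beads need not remove, remains a candidate source, and expression by the tumour line itself was not tested.

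Genes of chromosome 7 were lower in PERK-deficient tumours: of 437 expressed genes 187 fell and 14 rose, with a median of -0.36 against -0.07 on the other autosomes. Per library the difference was -0.28 (exact permutation p = 0.0286, adjusted over 20 chromosomes 0.143), and the lowest of the other autosomes was at -0.09. Dilution of tumour RNA by other cells would move every chromosome alike only if both had the same relative copy numbers. Copy numbers were not measured, so these values cannot decide on dilution. Of the difference 98.3% was kept once the trend with GC content and transcript length was removed, which argues against these. All 8 bins of 20 Mb lay below the other autosomes, so a copy number difference of the whole chromosome between the tumour lines may be the cause; DNA was not analysed here. Chromosomes 6 (0.18), 15 (0.16) and 14 (-0.09) also separated the groups at an exact permutation p = 0.0286, and the 4 melanocyte markers on chromosome 7 had a median of -0.97 against -0.43 for the other 19.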

How the results depend on the processing

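The settings that leave out PERK_KO libraries 2 and 3, PERK_KO library 4 with scramble library 4, or the mitochondrial genes, and the pan-leukocyte covariate, were chosen after the data were seen. RLE factors, upper-quartile factors and library totals left the direction and call as they were for 89 genes. These are the genes that the naming rule took and the report writes out. Calls that did not change with the settings had been preferred among them, so their stability says little about other genes. These factors were not run one by one for the other genes of the closing section. Of the 32 lists, 31 kept their direction and call under each of these factors and 26 with fry. With an estimated correlation 7 kept them and 25 lost their call, and 0 lists passed against 25 at the preset correlation. Between 23 and 26 lists passed when any 1 library was left out, and 14 to 22 list scores separated the groups.

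The count of called genes ran from 1078 to 2616 when any 1 library was left out, with 639 to 1372 higher and 439 to 1244 lower, each from 7 libraries in place of 8. DESeq2 called 2069 genes higher, upper-quartile factors left 653 lower and the stricter low-count filter, which tested fewer genes, left 612 lower; the cause was not tested for the first and second. Without a low-count filter, which tested more genes, the calls of Ly6c2 (adjusted p = 0.0606), Csf1r (0.0593), Naalad2 (0.0691), Tph2 (0.0804), Raet1e (0.0555), Lum (0.104) and mt-Nd2 (0.101) ended. At least 2-fold changes numbered 1049, of them 130 lower. Leaving out PERK_KO library 4 and scramble library 4 gave 1279 genes, 779 higher and 500 lower, from fewer libraries.

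The replicate numbers 2, 3 and 4 occur in both groups. The residual correlation of libraries that share a number ran from -0.20 to 0.10, and 1 of 3 scramble libraries was closest to the library of its own number, so the numbers were not taken as pairs. With the number as a block 199 genes were called, 139 higher and 60 lower. The same 6 libraries without the block gave 1334 genes, of them 421 lower.

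With the melanocyte score as a covariate edgeR called 0 genes, 0 higher and 0 lower, with 1290 at an unadjusted p under 0.05, and 9 lists passed; other tools were not run with it. The score had 95.7% of its variance between the groups, so the covariate takes up the comparison itself. The fitted log2 changes that turned sign under it were Ccr2 -0.56, Ly6c2 -5.33, Tcf7 -1.39, Irf8 -0.65, Csf1r -0.16, Irf7 -3.89, Isg15 -1.16, Fstl4 2.51, Naalad2 5.40, Tph2 0.83, Pou3f2 1.56, Rsad2 -0.0141, Trim30a -0.51, Iigp1 -1.08, H2-D1 -0.19, B2m -0.94, Tap1 -0.68, H2-Ab1 -1.33, Folr2 -0.76, Runx1 -0.60, Lmo2 -1.76, Cd3e -6.99, Ccl5 -0.22, Klrk1 -0.83, Trpm1 0.0276, Atf3 -0.57, Lgals9 -0.91, Ncf1 -0.15, Cxcl16 -0.19, Tnfaip3 -0.25, Ccl8 -0.52, Egr1 -1.29 and Zfp36 -1.10, none of them called. The lists that turned, with their camera adjusted p, were type I interferon 0.0243, MHC class I presentation 0.0308, MHC class II presentation 0.425, monocyte 0.806, macrophage 0.228, granulocyte-monocyte progenitor granule genes 0.701, basophil and eosinophil 0.402, T cell 0.632, cytotoxic and NK cell 0.262, erythroid 0.381, adipocyte 0.99, integrated stress response 0.244, myeloid suppressor effector genes 0.815, NF-kB inflammatory cytokines and chemokines 0.385 and dissociation and immediate early genes 0.0513.

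With the pan-leukocyte covariate 28 genes were called, 20 higher and 8 lower, and 8 lists passed, with 74.6% of the variance of that score between the groups. The log2 changes that turned were Itgam -0.30, Irf7 -0.95, Cd3e -3.22 and Cdh5 -0.84, none called, and the lists that turned, with their camera adjusted p, were type I interferon 0.786, basophil and eosinophil 0.711, T cell 0.258, B cell and plasma cell 0.786, endothelial 0.115, erythroid 0.958, adipocyte 0.955 and dissociation and immediate early genes 0.0207.

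Endothelial results had no steady direction, and the cause was not tested. Over 20 settings of the list tests the endothelial list kept its direction and passed in 3, with a lowest adjusted p of 0.00493, and it turned in 5. Without any 1 library the list's camera adjusted p ran from 0.0508 to 0.793, its score difference from -0.38 to 0.51 and the Cdh5 change from -0.0606 to 0.53. The list turned lower without PERK_KO libraries 2 and 3 (0.268) and without PERK_KO library 4 and scramble library 4 (0.584), where Cdh5 was at -0.28 and -0.0202. Its score difference was -0.0758 with a prior count of 0.5 and -0.0584 with library totals.

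Depth limits the lowest values: 3 counts correspond to 0.0529 CPM in the deepest and 0.103 CPM in the shallowest library. On simulated counts of the same depths the test recovered 32% of genes changed 1.5-fold, 66% of those changed 2-fold and 76% of those changed 8-fold. The changed genes were drawn above a minimum mean CPM and were fewer than the calls in the data, and genes varied independently. Recovery at the lowest levels was therefore not simulated.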

Other observations

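The genes and the list in this part were chosen after their values were seen, and none is offered with an explanation.

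Xist, the RNA of the inactive X chromosome, was at 21.4 ± 10.4 CPM (SD, n = 4) in scramble and 131 ± 68.5 CPM (n = 4) in PERK-deficient tumours, a log2 change of 2.62 (edgeR adjusted p = 0.0227).

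Next to Fndc3c1 on the X chromosome, Lpar4 (106920625 to 106933900) and Itm2a (107397099 to 107403376) had 636 and 205 counts over the scramble libraries and none in PERK-deficient libraries, at least 155-fold and 50.5-fold lower against a floor of 3 counts over the group. Pgk1 (106187100 to 106203699) on one side was at 731 and 654 CPM (edgeR adjusted p = 0.248), and 2610002M06Rik (107782751 to 107816334) on the other at 53.1 and 43.1 CPM (adjusted p = 0.213). Beyond Pgk1, Atp7a and Magee1 were called lower (log2 change -0.49 and -1.76, edgeR adjusted p = 0.0103 and 0.0199) and Tlr13 higher (2.09, adjusted p = 0.0255). Between Pgk1 and 2610002M06Rik the leukocyte receptors Cysltr1 and P2ry10 rose by 2.81 and 4.58. Over all chromosomes 29 genes called lower had no count in PERK-deficient libraries and 17 called higher had none in scramble libraries.

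Of 18 mammary secretory genes listed, 10 were tested, and of these 7 were higher, and 10 when adjusted over the list alone. The tested genes had a median of 5.70 (camera adjusted p = 0.00697 with an estimated correlation). Csn3 and Wfdc18, also in the list, had already stood among the 10 highest calls. Together the 10 tested genes took 5.84 CPM in scramble and 171 CPM in PERK-deficient tumours. Of the list's genes 2, Ltf and Lcn2, were also in the neutrophil list, and 2 reached 1 CPM in scramble libraries, so the rest had little room to fall. Csn2, Csn1s2a, Csn1s2b and Olah had no count in any library, and Csn1s1, Wap, Cel and Glycam1 did not pass the filter.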
